A study of Mus musculus and Homo sapiens with 13 samples.

How the data were processed

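Single-cell RNA sequencing was applied to polymorphonuclear neutrophils (PMN) obtained by cell sorting. The 13 libraries comprised 9 from mice and 4 from people. In mice there were 3 libraries each of PMN from the spleen of naive animals, from the spleen of tumour-bearing (TB) animals and from the tumours of TB animals. In people there were 2 libraries of blood PMN from healthy donors and 2 from patients with a tumour. Libraries were made with the 10x Genomics 3' chemistry, in which each transcript carries a unique molecular identifier (UMI), so that PCR copies of a molecule are counted once. The labels numbered mouse replicates 2 and 3, and the remaining library of each group was taken as replicate 1. The labels did not say that libraries of a group came from separate animals or donors. The p-values of the group comparisons thus measure the spread between these libraries, which may be technical.

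The deposited matrices hold whole-number UMI counts per gene and barcode, which the authors made with Cell Ranger 3.1.0 on mm10 for mouse and hg19 for human, per the submitters' processing notes. The gene annotation and the aligner settings were not given in the sources used here. The mouse files name genes by symbol and the human files by Ensembl identifier without symbols. No table that pairs the human identifiers with names was used here, so human cells could not be assigned to classes or gene lists.

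Mouse replicate 1 used another set of cell barcodes and another gene annotation than replicates 2 and 3. A total of 300 pairs of old and new symbols were joined, and the 16467 genes present on both sides were used. This left out 0.296% of UMIs in replicate 1 and 0.259% in replicates 2 and 3. Barcodes were kept with at least 300 UMIs, at least 150 genes and, in mouse, at most 10% mitochondrial UMIs. Of 66854 deposited mouse barcodes 66473 passed, and of 11190 human barcodes 11175 passed. The mouse cells of all libraries were clustered together on 1500 variable genes and 30 principal components by the Leiden method on a graph of 20 nearest neighbours at resolution 0.8 (leidenalg 0.10.2, scikit-learn 1.9.0). A cluster was named neutrophil-like where at least 10% of its UMIs fell in the fixed neutrophil markers and fewer than 3 markers of other classes stood among its 50 leading genes. Other classes needed 3 of their own markers there. These thresholds were set after the clusters were seen. They kept 4 mixed clusters unnamed, which held 0.544% of barcodes in naive spleen, 0.722% in TB spleen and 1.97% in tumour. In all, 15 of 27 clusters were neutrophil-like and held 59013 cells. Scrublet, as provided in scanpy 1.11.5, called 0 doublets in 8 libraries and 11 barcodes in naive spleen replicate 3, none of them neutrophil-like. At that rate it did not work as a doublet filter, so cells carrying at least 2 markers of another class were left out as an alternative instead.

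UMI counts of the neutrophil-like cells were summed per library. The 3 mouse groups were compared in 1 fit over the 9 libraries with a mean per group, by edgeR 4.0.16 (R 4.3.3) with its quasi-likelihood test, TMM normalisation, its default filter on low counts (filterByExpr) and Benjamini-Hochberg adjustment at a false discovery rate of 0.05. Adjusted p-values given for genes come from this test. Levels are means of CPM (UMI counts scaled to a common library size, with TMM factors) with the SD over 3 libraries. Standard errors of log2 fold changes were derived as the size of the fold change divided by the square root of the F statistic, and were not given where F was close to 0. The human test was planned for neutrophil-like cells as well, but without gene names no class could be assigned, so human UMI counts were summed over all barcodes that passed the filter and tested in the same way. A set of 22 human gene identifiers (the X-inactivation genes and Y-linked genes) was left out of every human table.

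To ask about classes within a group, each neutrophil-like cell was thinned at random to 500 UMIs and the cells of a library were divided into those with and those without a Cd14 UMI. The sums of both parts were compared with the library as a block, in libraries with at least 20 cells in each part, with Cd14 itself left out. The p-values there rest largely on a spread pooled over genes. They do not measure how the difference of a gene varies between the few libraries. CD14 is the marker that the study's authors used for polymorphonuclear myeloid-derived suppressor cells (PMN-MDSC), so it is no independent choice. Shares of cells with a UMI were taken from the thinned cells and compared by two-sided exact permutation tests over libraries, with Clopper-Pearson intervals at a confidence level of 95% per library. With 3 libraries against 3 the smallest p such a test can give is 0.1. Intervals and limits cover counting error only.

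Before the data were examined, the tests, the groups, the cell type markers, 15 gene lists, the rule for named genes and most alternatives were fixed. The lists were PMN-MDSC-associated genes, primary granules, secondary and tertiary granules, mature neutrophil surface proteins, interferon response, inflammatory cytokines and NF-kB targets, endoplasmic reticulum (ER) stress, hypoxia, glycolysis, oxidative phosphorylation, lipid uptake and storage, NADPH oxidase and redox, MHC class I presentation, cell cycle, and immediate early and dissociation genes. Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. Named genes had an adjusted p below 0.05, an absolute log2 fold change of at least 1, at least 50 CPM in the higher group and no overlap of libraries. Their CPM in the other cells of the higher group was at most 10 times that in the neutrophil-like cells. Ribosomal, mitochondrial, histone, immunoglobulin, T cell receptor, haemoglobin, predicted and sex-linked genes were excluded. The 12 genes with the largest fold change in each direction were taken (8 in the Cd14 comparisons, where the non-overlap and other-cell conditions were replaced by a like sign in every library), with 2 to 4 members per list. Cd14, Arg1, Arg2, Il1b and Olr1 were always given. For TB spleen against naive spleen, where no gene passed, the rule was applied to the fit with replicate number as a block. Coordinates are 1-based positions on GRCm38, the assembly of mm10, from the GENCODE vM21 annotation, which held 211 of the 211 named genes.

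Whether replicate numbers pair the libraries was checked from the correlation over genes of their deviations from the group means. Naive and TB spleen libraries of the same number correlated at 0.584, 0.37 and 0.26, and TB spleen and tumour libraries at 0.522, 0.316 and 0.15, so every pair lay above 0.1, the bound for taking the numbers to pair the libraries. Across replicates 2 and 3, libraries of different number correlated at -0.036 and -0.055 between naive and TB spleen, but at 0.331 and 0.173 between TB spleen and tumour, so there the number did not pair these libraries beyond their shared barcode set. Tumour and naive libraries correlated at 0.371, 0.266 and 0.037 and were not taken as paired. The planned fit, the simulations and the other splits hold no pair term, and the fit with replicate number as a block is given beside them. The pairing comes from the labels' numbers for replicates 2 and 3 and from elimination for replicate 1. Libraries were also checked for duplicates. Tumour replicates 2 and 3 differed by a chi-square of 2.64 per gene, above the 1.75 that was the highest of 20 random divisions of their pooled cells, against 12.6 to 361 for the other pairs within a group. They were kept as separate libraries, and summing them was tried as an alternative, since the tumour group may hold fewer than 3 independent libraries.

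The models were tested on simulated data with 200 genes changed, drawn from the real means and library sizes. At a log2 fold change of 2, 52.5% of the changed genes were recovered for TB spleen against naive spleen (10184 genes), 69.5% for tumour against TB spleen (10228 genes) and 58% for tumour against naive spleen (10220 genes). At a log2 fold change of 1, none were recovered in those 3 comparisons. The Cd14 comparisons recovered 83% in TB spleen (5590 genes) and 92.5% in tumour (5589 genes) at a log2 fold change of 1. Their changed genes were drawn at a higher minimum CPM than in the group comparisons, so these shares are not like for like. At a log2 fold change of 2, false calls numbered 1, 12 and 10 in the 3 group comparisons in the order above. In the Cd14 comparisons of TB spleen and tumour they numbered 15 and 8. The human comparison recovered none at a log2 fold change of 1 (12976 genes) or 2 (12983 genes). Alternatives tried were DESeq2 1.42.0, size factors of the DESeq2 type (RLE), no scaling factor, no filter on low counts, no cell filter, a stricter cell filter, all barcodes whatever their class, cells without those Scrublet called, thinned cells, other thinning depths, replicate number or barcode set as a block, replicates 2 and 3 alone, only the groups compared, and leaving out each library. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.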

Results

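PMN were profiled in 9 mouse and 4 human libraries. In naive spleen the 3 libraries held 11025, 5622 and 444 barcodes with 51168842, 10329999 and 702012 UMIs. In TB spleen they held 12794, 8246 and 1374 barcodes with 84402872, 20730286 and 2949681 UMIs. In tumour they held 8522, 9110 and 9717 barcodes with 40888698, 31321567 and 33215713 UMIs. The healthy blood libraries held 2740 and 1309 barcodes with 2202813 and 4628465 UMIs, and the patient libraries 3192 and 3949 barcodes with 9020931 and 10080656 UMIs. The median UMI count per barcode ranged from 1220 to 4205.5 in mouse and from 452 to 3007 in human. The series asks whether classical neutrophils and PMN-MDSC, neutrophils that suppress immune responses in cancer, occur side by side in one host.

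Neutrophil-like cells made up most barcodes in TB spleen (94.2% ± 0.952, SD, n = 3) and in tumour (91.1% ± 5.33, n = 3), and fewer in naive spleen (62.5% ± 27.2, n = 3). The naive mean covered a wide spread, since replicate 1 held 93.2% and replicates 2 and 3 held 53.3% and 41.1%. In the latter 2 libraries, monocyte or macrophage-like cells made up 21.1% and 44.0% and B or plasma cell-like cells 24.8% and 13.9%. Tumour libraries held 5.36% ± 3.5 monocyte or macrophage-like cells and 0.716% ± 0.0291 stromal, endothelial or epithelial-like cells, the latter against 0.004% ± 0.00693 in TB spleen. The smallest p in the 24 class comparisons was 0.1 by exact permutation, the lowest that 3 libraries against 3 allow (adjusted p at least 0.48). A sort preceded these shares and can set them.

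**Figure D1:**
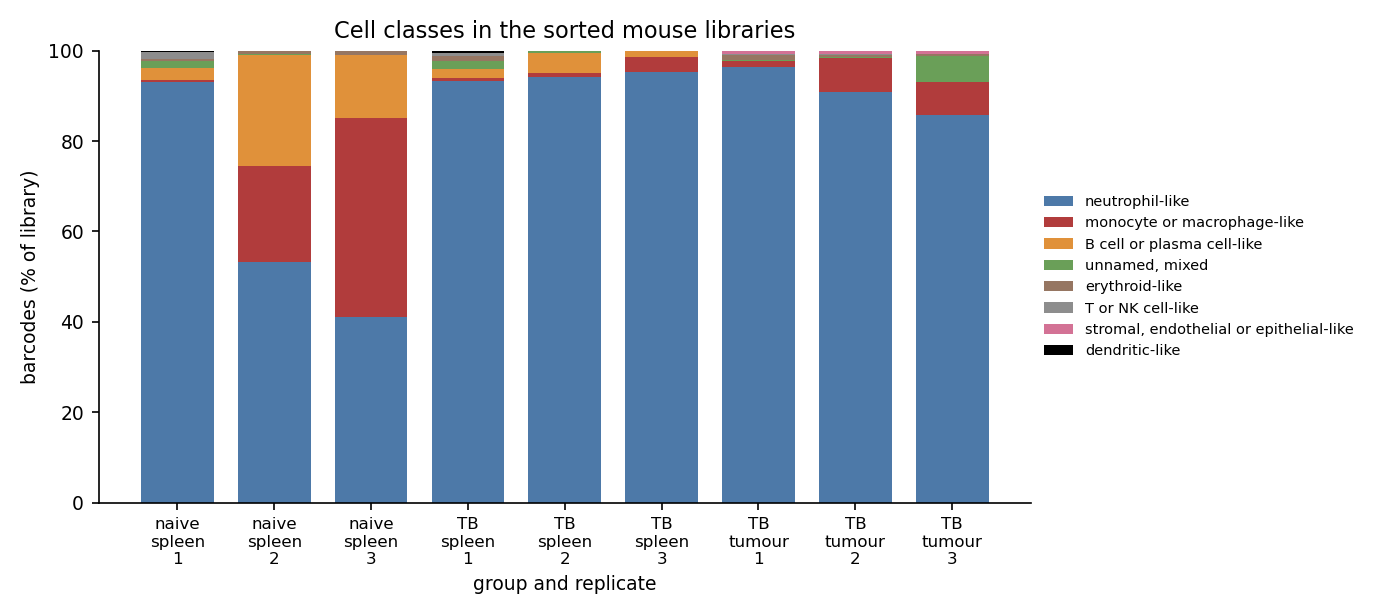
Share of barcodes that passed the filter (percent, y axis) in each cell class for the 9 mouse libraries (x axis), with 1 stacked bar per library. Neutrophil-like cells form most of every TB library, while naive spleen replicates 2 and 3 stand at 53.3% and 41.1%.

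The first comparison asked how neutrophil-like cells of the spleen differ between TB and naive mice. Prok2, a chemokine-like ligand induced in neutrophils by G-CSF, stood at 212 ± 137 CPM in TB spleen and 8.36 ± 6.06 in naive spleen (n = 3 each), and Upp1, a uridine phosphorylase, at 175 ± 77.5 and 23 ± 11. Cd14, a co-receptor for lipopolysaccharide, stood at 88.3 ± 15.5 and 29 ± 11.3 CPM (log2 fold change 1.60 ± 0.34, SE; adjusted p = 0.246). Arg2, Il1b and Olr1 had log2 fold changes of 0.48 ± 0.21, -0.03 ± 0.35 and -0.32 ± 0.45, and Arg1, the arginase of macrophages and human neutrophils, had 0 UMIs in both groups. None of 10611 genes passed edgeR's quasi-likelihood test, against 756 at an unadjusted p under 0.05 and 55 (42 higher, 13 lower) by DESeq2. With replicate number as a block, 97 genes were higher and 35 lower in TB spleen. Within replicates 2 and 3 alone, which share a barcode set, 18 genes were called (1 higher, 17 lower), and with barcode set as a block 67 were. Without TB spleen replicate 3, edgeR called 1 gene, Lipg, an endothelial lipase, named here after its value was seen.

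In the blocked fit, 45 higher and 2 lower genes met the naming rule. Prok2 (log2 fold change 4.37 ± 0.43, adjusted p = 0.00144; 0.087 without the block) and Upp1 (2.79 ± 0.31, 0.00164; 0.087 without) were among the higher ones. The interferon-induced transmembrane genes Ifitm1 (2.12 ± 0.43) and Ifitm6 (1.88 ± 0.26), the fatty acid binding protein gene Fabp5 (1.86 ± 0.28), the mitochondrial membrane protein gene Tspo (2.10 ± 0.28) and the glycoprotein gene Lrg1 (1.84 ± 0.27) rose as well. Igfbp6, Steap4, Plscr1, Asnsd1 and BC100530 rose by 1.70 to 3.17. The lower genes were Mpeg1, which encodes the pore-forming perforin-2 (-1.21 ± 0.25), and Jaml, an adhesion molecule gene (-1.03 ± 0.21). Cd14 passed in that fit (1.67 ± 0.30, adjusted p = 0.02), as did Nos2 (5.78 ± 0.70, 0.00357), the inducible nitric oxide synthase, which stood at only 1.63 ± 1.39 CPM in TB spleen. Granule gene Lcn2 (1.39 ± 0.29, 0.0355), interferon gene Ifitm3 (1.45 ± 0.28, 0.0269), hypoxia genes Hilpda (2.47 ± 0.47) and P4ha1 (2.19 ± 0.45), glycolytic Pfkl (1.60 ± 0.31) and the glutathione synthesis gene Gclm (1.60 ± 0.24) also passed with the block and not without it. Barcode set as a block called Cd14, Nos2, Hilpda, Pfkl and Gclm as well, and DESeq2 called Cd14, Nos2, P4ha1 and Gclm.

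Of the fixed lists, camera called 6 higher in TB spleen than in naive spleen, with no member called over all genes in the fit without a block. Secondary and tertiary granule genes had a median log2 fold change of 0.77 (adjusted p = 5e-06), glycolysis 0.79 (5.77e-07), oxidative phosphorylation 0.28 (0.00654), cell cycle 0.59 (0.00106), hypoxia 0.64 (0.0125) and NADPH oxidase and redox 0.28 (0.0292). All 6 calls were lost with an estimated correlation, with an adjusted p of 0.403 for granule, glycolysis, hypoxia and redox genes, 0.618 for oxidative phosphorylation and 0.517 for cell cycle. Fry, which asks whether a list's genes move on balance one way and compares them with no other genes, called none of the 6 (adjusted p from 0.141 to 0.435). Adjusted over the list alone, 5 glycolysis genes, 4 hypoxia genes, 2 PMN-MDSC-associated genes, 2 interferon genes, 2 lipid genes and 1 redox gene passed as higher, and 1 hypoxia gene as lower. Camera called none of the other 9 lists (adjusted p from 0.0705 to 0.932). The PMN-MDSC list holds the authors' own marker, Cd14, and is not independent evidence. Naive replicates 2 and 3, with their lower share of neutrophil-like cells, contributed 2942 and 169 neutrophil-like cells. In those libraries markers of other classes stood in the neutrophil-like cells at 6.46% and 6.42% of their level in the other cells, against 0.24% in replicate 1.

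The second comparison asked how neutrophil-like cells in the tumour differ from those in the spleen of TB mice. Inflammatory chemokine and cytokine genes rose steeply in tumour. Cxcl2 (76800 ± 11900 CPM against 211 ± 251), Cxcl3 (8570 ± 3210 against 0.459 ± 0.648) and Cxcl1 (168 ± 63.2 against 0.245 ± 0.316), which encode ligands of the neutrophil receptor CXCR2, rose by 8.50 ± 1.60, 14.03 ± 1.02 and 11.22 ± 0.99 on the log2 scale. Ccl3 (9.95 ± 1.06), Ccl4 (9.35 ± 0.85) and Il1a (12.89 ± 0.90) rose with them. Cd14 rose from 88.3 ± 15.5 to 9990 ± 699 CPM (6.82 ± 0.42, adjusted p = 6.2e-06; n = 3 each). Genes of neutrophil granules that fell included Camp, which encodes the antimicrobial peptide cathelicidin (14900 ± 4960 to 96.3 ± 23.7 CPM; -7.27 ± 0.60), and Ltf, which encodes lactoferrin (3550 ± 1190 to 68.5 ± 4.63; -5.70 ± 0.60). Of 15 secondary and tertiary granule genes 8 fell and 1, the metalloprotease gene Adam8 (2.50 ± 0.32), rose, and the list's call was lost at an adjusted p = 0.196 with an estimated correlation. Clusters 6 and 9, led by granule genes, differed in share. Cluster 6 held 20.5% of neutrophil-like cells in TB spleen replicate 1, and cluster 9 held 19.2% and 7.98% in replicates 2 and 3. In tumour either cluster held at most 0.05%. Their cells carried a median of 3.62 and 2.27 times their library's median UMIs. Falls in summed counts thus do not show a fall per cell. By position, Cd14 lies on chromosome 18 (36725067 to 36726798), Cxcl2 on chromosome 5 (90903871 to 90905938), Camp on chromosome 9 (109847379 to 109849617) and Ltf on the same chromosome (111019271 to 111042767).

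In total 2972 genes were called, 1887 higher and 1085 lower in tumour, and 739 higher and 128 lower ones met the naming rule. The remaining genes with the largest rises among those that met the rule were Hilpda, an inhibitor of lipid breakdown induced by hypoxia (11.19 ± 0.74), the cell cycle inhibitor Cdkn1a (9.82 ± 0.77), the heat shock gene Hspa1a (9.24 ± 0.38), osteopontin gene Spp1 (8.72 ± 0.50), the transcription regulator Tgif1 (8.54 ± 0.68) and thrombospondin gene Thbs1 (8.22 ± 0.69). The largest falls that met the rule also included the granule genes Ngp (-5.14 ± 0.53), Chil3 (-4.92 ± 0.79) and Itgb2l (-3.74 ± 0.48), Cebpe, the transcription factor that drives granule genes (-4.85 ± 0.46), Orm1 (-4.42 ± 0.68), the protease inhibitor Serpinb1a (-3.98 ± 0.71), Golim4 (-3.76 ± 0.48), Zmpste24 (-3.66 ± 0.52), the cell cycle gene Ube2c (-4.61 ± 0.65) and Cybb, the catalytic subunit of the NADPH oxidase (-3.51 ± 0.61). The arginase gene Arg2 rose from 133 ± 4.62 to 785 ± 53.4 CPM (2.56 ± 0.22), Il1b from 1670 ± 493 to 27000 ± 4700 (4.01 ± 0.40) and Olr1, which encodes the oxidised lipoprotein receptor LOX-1, from 5.29 ± 1.30 to 41.2 ± 26.5 (2.97 ± 0.45). Arg1, with 0 UMIs in both spleen groups, was at least 2940-fold higher in tumour, against a floor of 3 counts over the group. Its tumour CPM was 0.844, 117 and 136 in replicates 1 to 3, and plain CPM in the neutrophil-like cells stood at only 0.0143 to 0.018 times that in the macrophage-like cells of the same libraries.

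**Figure D2:**
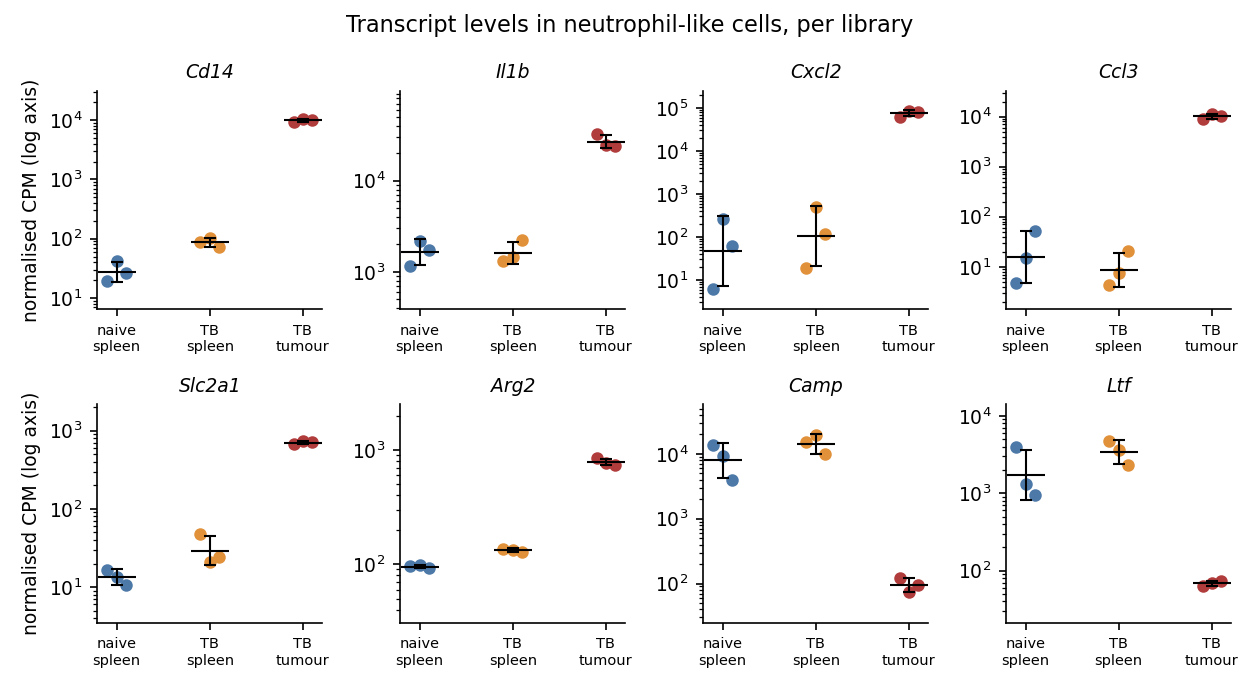
TMM-normalised CPM (y axis, log scale) of 8 genes in neutrophil-like cells of naive spleen, TB spleen and TB tumour. Points are libraries (3 per group) and bars are the mean and SD of their log2 values. Cd14, Il1b, Cxcl2, Ccl3, Slc2a1 and Arg2 lie higher in tumour than in either spleen group, and Camp and Ltf lower.

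The fixed lists grouped these changes. Of 20 measured cytokine and NF-kB target genes 19 rose and none fell (median log2 fold change 4.27; adjusted p = 0.00687 with an estimated correlation), among them Nfkbia, the inhibitor of NF-kB (5.56 ± 0.34). Of 17 hypoxia genes 15 rose (4.1; 0.00541), including the glucose transporter gene Slc2a1 (4.50 ± 0.37) and Vegfa (5.05 ± 0.40), which encodes an angiogenic factor. Of 17 glycolysis genes 14 rose (1.72), such as Pfkfb3 (4.18 ± 0.36) and Tpi1 (3.82 ± 0.38), a call that was lost at an adjusted p = 0.0617 with an estimated correlation. Of 18 ER stress genes 12 rose (2.15; 0.00687), including Atf3 (6.93 ± 0.42) and Ddit3, which encodes CHOP (3.29 ± 0.28). Of 16 lipid genes 10 rose (1.95; 0.0108), such as the lipid droplet gene Plin2 (4.71 ± 0.40) and the sterol exporter gene Abca1 (4.57 ± 0.50). Of 15 mature surface genes 8 rose (1.93; 0.00722), including Trem1 (4.20 ± 0.33) and the decoy receptor gene Il1r2 (4.53 ± 0.36), while Cxcr2 had a log2 fold change of -0.20 ± 0.28. Of 16 immediate early and dissociation genes 15 rose (3.48; 0.0235), among them Jun (4.96 ± 0.39) and Hspa1a. Adjusted over the list alone the counts were 19, 15, 14, 14, 10, 8 and 16.

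Of 14 measured PMN-MDSC-associated genes 12 rose and none fell (median 3.65; adjusted p = 0.00687 with an estimated correlation; 12 adjusted over the list alone), including Cd274, which encodes the checkpoint ligand PD-L1 (6.20 ± 0.46), while Cd84 stood at -0.25 ± 0.26. This list includes the marker the authors chose and is not independent evidence. Of 19 interferon genes 11 rose (1.44; 12 adjusted over the list alone), among them Isg15 (2.99 ± 0.34) and Rsad2 (2.80 ± 0.40), and the list's call was lost at an adjusted p = 0.12 with an estimated correlation. The secondary and tertiary granule list had a median of -1.17 (9 lower and 1 higher adjusted over the list alone), and its largest fall was Fcnb, which encodes ficolin B (-9.25 ± 0.90). Of 17 cell cycle genes 12 fell (median -3.03; 12 lower and 1 higher adjusted over the list alone), such as Ccnb2 (-4.29 ± 0.50) and Ccna2 (-4.09 ± 0.66), with Pcna at 1.58 ± 0.56. Both lists gave an adjusted p = 0.196 with an estimated correlation. Cluster 17, led by cell cycle genes, held 2% of neutrophil-like cells in TB spleen replicate 1, and cluster 19 held 2.98% in replicate 2. No neutrophil-like tumour cell fell in them, so the cell cycle falls need not be falls per cell. Only 2 primary granule genes were measured, of which Ms4a3 fell (-5.35 ± 1.06) and Prtn3 stood at -0.29 ± 0.65. Lists going both ways were oxidative phosphorylation (2 higher, 3 lower of 22; camera adjusted p = 0.203) and NADPH oxidase and redox (6 higher, 2 lower of 17; 0.138). In the former Cycs rose (2.40 ± 0.38) and Ndufb8 fell (-1.20 ± 0.26), and in the latter Srxn1 (4.85 ± 0.36) and Sod2 (4.21 ± 0.44) rose while Cybb fell. Of 11 MHC class I genes 3 rose (0.256), H2-K1 (1.54 ± 0.32), H2-D1 (1.01 ± 0.28) and Nlrc5 (1.96 ± 0.43), each count the same when adjusted over the list alone. Fry called redox genes (adjusted p = 0.00124) and MHC class I genes (0.0128) higher.

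**Figure D3:**
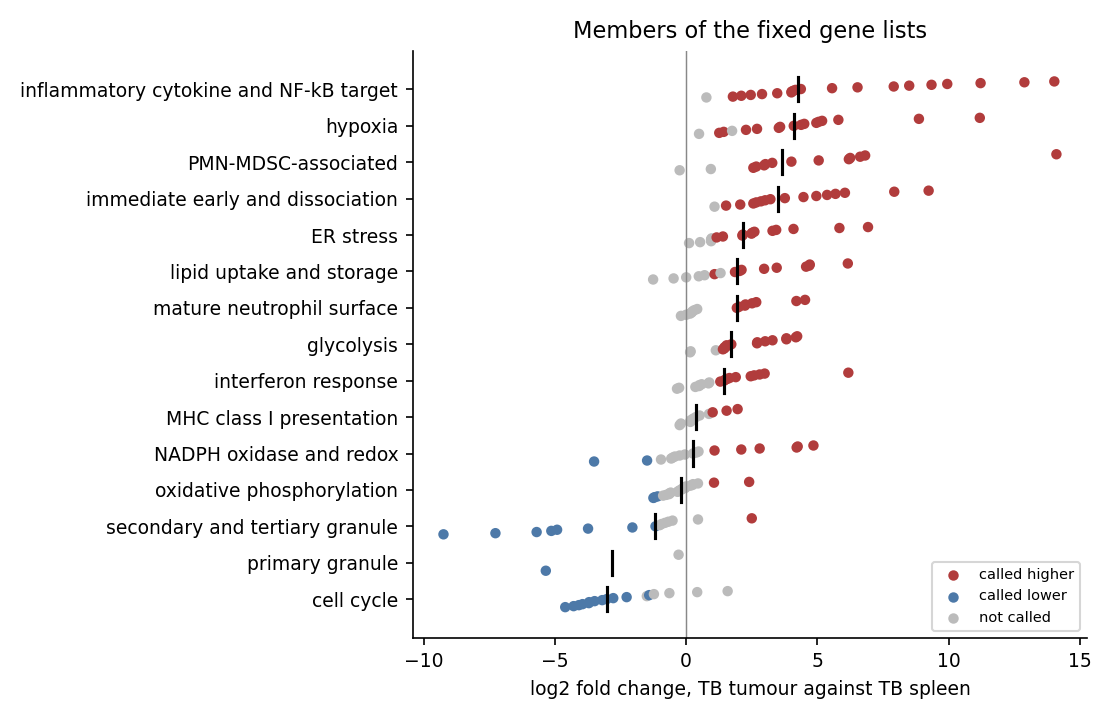
Log2 fold change (x axis) of the measured members of the 15 gene lists (y axis), TB tumour against TB spleen, in neutrophil-like cells. Points are genes, red where called higher, blue where called lower and grey where not called, and the black bar is the list's median, which runs from -3.03 for cell cycle to 4.27 for cytokines.

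With replicate number as a block, 4693 genes were called between tumour and TB spleen (2715 higher, 1978 lower). Replicates 2 and 3 alone, which share a barcode set, gave 4061 calls, and the other set holds 1 library per group, too few for a test. The count fell to 1912 without tumour replicate 2 and to 1966 without tumour replicate 3, to 2020 with those 2 libraries summed, and to 1762 with each cell thinned to 500 UMIs. Neutrophil-like cells clustered by library as well as by group. The cluster with most of a library's neutrophil-like cells was cluster 2 in naive spleen replicate 1 (78.1%) and cluster 7 in replicates 2 and 3 (78.7% and 80.5%), clusters 0, 4 and 7 in TB spleen replicates 1 to 3 (76.1%, 74.6% and 77.4%), and cluster 5 in tumour replicate 1 (58.4%) and cluster 1 in replicates 2 and 3 (51.4% and 51.8%). With no scaling factor, which moved the median log2 fold change of all genes to -0.619, 1114 genes were higher and 2840 lower, so that 28.2% of calls were higher against 63.5% with TMM.

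The remaining comparison set tumour against naive spleen. It is not independent of the other comparisons, since it uses the same libraries. Cd14 rose from 29 ± 11.3 to 9990 ± 699 CPM (8.42 ± 0.45, adjusted p = 4.94e-06; n = 3 each), Nos2 by 11.73 ± 0.81, Arg2 by 3.04 ± 0.23, Il1b by 3.98 ± 0.40 and Olr1 by 2.64 ± 0.47. Arg1 was at least 2180-fold higher and Cxcl1 at least 4330-fold higher, both against 0 UMIs in naive spleen. The largest other rises that met the naming rule were Cxcl3 (16.56 ± 1.21), Hilpda (13.68 ± 0.88), Il1a (11.89 ± 0.94), Cdkn1a (10.49 ± 0.82), Ciart (10.17 ± 0.79), Hspa1a (9.94 ± 0.42), Cxcl2 (9.39 ± 1.66), the serum amyloid gene Saa3 (9.10 ± 1.29), Ccl3 (9.05 ± 1.04) and Fosl1 (8.93 ± 0.66). Camp (-6.55 ± 0.58), Ltf (-4.93 ± 0.58), Chil3 (-4.38 ± 0.77), Ngp (-4.03 ± 0.50), Cebpe (-3.94 ± 0.44), Itgb2l (-3.19 ± 0.47) and Cybb (-3.15 ± 0.60) fell, as did Serpinb1a, Lta4h, AI467606, St3gal5 and Adpgk (-2.79 to -2.49). Cluster 6 held 15.6% of neutrophil-like cells in naive spleen replicate 1, and cluster 9 held 9.08% and 4.73% in replicates 2 and 3. These falls in summed counts thus need not be falls per cell.

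In total 3023 genes were called (1891 higher, 1132 lower), and 862 higher and 108 lower ones met the naming rule. Members rose in cytokine and NF-kB (19 of 20), hypoxia (14 of 17), glycolysis (15 of 17), ER stress (12 of 18), lipid (11 of 16), mature surface (8 of 15), immediate early (15 of 16) and PMN-MDSC-associated lists (13 of 14, the list with the authors' marker and not independent evidence). All 8 lists kept their call with an estimated correlation (adjusted p from 0.00772 to 0.0202). Adjusted over the list alone these counts were 19, 14, 15, 12, 11, 9, 16 and 13 higher, with 1 lipid gene lower. Of 19 interferon genes 14 rose (16 adjusted over the list alone; adjusted p = 0.0767 with an estimated correlation). Of 15 secondary and tertiary granule genes 6 fell and 1 rose (the same adjusted over the list alone; 0.34 with an estimated correlation), and of 17 cell cycle genes 10 fell (12 lower and 1 higher adjusted over the list alone; 0.334), neither called by fry (0.0564 and 0.0643). Redox genes went both ways (7 higher, 1 lower of 17; 7 and 2 adjusted over the list alone; adjusted p = 0.0856 with an estimated correlation), as did oxidative phosphorylation (2 higher, 2 lower of 22; camera adjusted p = 0.987). MHC class I had 2 higher of 11 (camera adjusted p = 0.571), and of 2 primary granule genes Ms4a3 fell (-4.66 ± 1.07). Ndufb8, lower here (-0.94 ± 0.26), had a log2 fold change of 0.22 when all barcodes were summed. The count of calls was 1960 without tumour replicate 2, 2010 without tumour replicate 3, 2060 with those 2 libraries summed, 2011 with thinned cells and 3369 in replicates 2 and 3 alone. With no scaling factor (median -1.089, and -0.454 for TB spleen against naive spleen) 869 genes were higher and 4657 lower, so that 15.7% of calls were higher against 62.6% with TMM.

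Shares of cells with a UMI were compared at an equal 500 UMIs per cell, a depth that left out no cell. A Cd14 UMI was found in 2.30% ± 0.463 of neutrophil-like cells in naive spleen, 5.35% ± 0.904 in TB spleen and 85.2% ± 4.75 in tumour (n = 3 each; 6.15%, 21.2% and 98.0% without thinning). The groups did not overlap in any pair, and the exact permutation p was 0.1 each, the smallest possible (adjusted p = 0.156 over 42 comparisons). In lymphocyte-like cells of the same libraries, which should lack the gene, 7 of 1890 (0.37%), 1 of 729 (0.137%) and 8 of 39 (20.5%) had a Cd14 UMI. Their median depths per library ran from 1777 to 7383.5 UMIs, against 1128 to 4261 in the neutrophil-like cells. From TB spleen to tumour the share was higher, with no overlap between libraries, for Cxcl2 (8.52% to 98.0%; 53.8% of lymphocyte-like cells in tumour), Ccl3 (0.6% to 57.5%; 7.69%), Il1b (58.3% to 92.2%; 25.6%), Arg2 (8.6% to 21.9%; 2.56%) and Cd274 (0.603% to 15.6%; 0 of 39 cells, a limit of 7.69%). For Vegfa (0.219% and 4.41%) and Olr1 (0.196% and 1.42%) the same limit lies above the tumour share, so these shares cannot be set apart from background. The share was lower for Camp (49.3% to 0.409%; 39.5% of lymphocyte-like cells in TB spleen), Ltf (27.6% to 0.595%; 95 of 729 such cells) and Cxcr2 (41.6% to 18.7%; 4.66%). The Cxcr2 difference appears at a fixed UMI total, while its TMM-normalised level was not called (-0.20 ± 0.28, adjusted p = 0.64). For Mki67 (0.388% and 0.0527%) the lymphocyte-like cells of TB spleen stood higher, at 0.823%. Ifit3 (2.21% and 2.75%) overlapped. Libraries of the compared groups were fully apart for 12 of 14 genes in each comparison with tumour, and for 3 of 14 between TB spleen and naive spleen. Of these Cd14 was higher in TB spleen, while Olr1 (a difference of -0.185 points) and Cd274 (-0.642) were lower and overlapped at 300 and 1000 UMIs and without thinning.

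Whether cells with a Cd14 UMI differ from the other neutrophil-like cells of the same library bears on the coexistence named in the series title. Without thinning, 6.15% of cells in naive spleen and 21.2% in TB spleen held a Cd14 UMI, against 2.30% and 5.35% at 500 UMIs. Most spleen cells in which Cd14 was detected thus lay in the part without a Cd14 UMI. The split does not separate 2 classes cleanly, and a gene not called there may still differ between them. In the Cd14 cells 7 of 15 granule genes were lower in naive spleen and 9 in TB spleen, where the list's call was lost at an adjusted p = 0.0642 with an estimated correlation and at 0.0745 by fry. In naive spleen Camp (-2.78 ± 0.18, adjusted p = 7.56e-49), Ltf (-2.79 ± 0.23), Chil3 (-3.13 ± 0.31; called in 5 of 7 alternatives) and Ngp (-2.45 ± 0.18) fell, as did Cybb (-2.32 ± 0.35; 6 of 7), Adpgk (-2.98 ± 0.61; 4 of 7) and Ifitm6 (-1.72 ± 0.24). Stfa1 (-1.74 ± 0.45) was called in 0 of 7 alternatives. In TB spleen Camp (-1.69 ± 0.13, adjusted p = 2.7e-37), Ltf (-1.72 ± 0.13), Ngp (-1.62 ± 0.12), Itgb2l (-2.12 ± 0.36), Cebpe (-1.90 ± 0.28), Anxa3 (-1.71 ± 0.32), Ethe1 (-1.39 ± 0.32) and Cybb (-1.93 ± 0.20) fell. Of these Cebpe, Anxa3 and Ethe1 were called in 5 of 8 alternatives, Itgb2l in 6, Camp in 7 and the others in all 8. With so few libraries, p-values this small come from a spread pooled over genes and not from each gene's own libraries. Higher in the Cd14 cells of naive spleen were the survival gene Bcl2a1b (2.15 ± 0.46) and Marcksl1 (1.23 ± 0.22), each called in 5 of 7 alternatives. The thioredoxin reductase gene Txnrd1 (2.03 ± 0.50) was called in 2 of 7 alternatives and Clec4n (1.46 ± 0.38) in 1. Il1b (-0.03 ± 0.17 and 0.22 ± 0.13) and Arg2 (-0.52 ± 0.34 and 0.18 ± 0.17) were not called in either spleen, Arg1 had no UMI there, and Olr1 was not called (38 UMIs outside the Cd14 cells of each spleen).

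In total 36 genes were called in naive spleen (9 higher, 27 lower) and 55 in TB spleen (2 higher, 53 lower) of 5901 tested. Adjusted over the list alone, 14 granule genes were lower in naive spleen (median -1.39; adjusted p = 0.0188 with an estimated correlation) and 11 in TB spleen (median -0.88). No PMN-MDSC-associated gene was called in either spleen by edgeR, and camera called that list higher in TB spleen (median 0.16, adjusted p = 0.0225), which was lost at an adjusted p = 0.446 with an estimated correlation. Camera also called cytokine (median 0.44) and interferon genes (0.16) higher and glycolysis (-0.39) and redox genes (-0.29) lower in naive spleen, and in TB spleen cytokine (0.09), interferon (0.06) and immediate early genes (0.16) higher and oxidative phosphorylation (-0.31) and redox genes (-0.18) lower. All 9 of these calls were lost with an estimated correlation (adjusted p from 0.316 to 0.627). The Cd14 cells numbered 184, 80 and 4 in naive spleen, so that replicate 3 was not used, and 752, 404 and 59 in TB spleen. Leaving out either used library of naive spleen leaves 1, with no spread of its own, so those counts are not given. The alternatives counted for naive spleen genes include these fits. TB spleen gave 10 calls without replicate 1 and 36 without replicate 2, and DESeq2 called 19 genes in naive spleen and 8 in TB spleen.

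In tumour, where most cells had a Cd14 UMI (6530, 7265 and 7292 with, 1658, 982 and 1008 without), 94 genes were higher and 165 lower in the Cd14 cells. Without thinning 98.0% of tumour cells held a Cd14 UMI, against 21.2% in TB spleen. Most tumour cells without one at 500 UMIs thus lost it by thinning, so this split sets more against less Cd14. Higher genes included Il1b at 0.67 ± 0.12 (adjusted p = 7.21e-06), Il1a at 0.75 ± 0.12, Csf3, which encodes G-CSF, at 1.42 ± 0.27, and the surface receptor genes Trem1 at 0.60 ± 0.10 and Fpr1 at 0.63 ± 0.11. Lower genes included the hypoxia genes Bnip3 at -0.58 ± 0.10, Ero1l at -0.57 ± 0.09 and Higd1a at -0.58 ± 0.10, as well as Cd274 (-0.53 ± 0.10), Hmox1 (-0.69 ± 0.09) and Hspa1a (-0.81 ± 0.10). Camp (-2.23 ± 0.25) and Ltf (-1.75 ± 0.24) were lower too, at low levels on both sides (18.6 ± 10.8 and 21.5 ± 4.69 CPM in the Cd14 cells). Ciart, Gpnmb, Rragd, Sap30, Mreg and Commd6 fell by 1.06 to 1.51. Mreg and Commd6 were called in 5 of 9 alternatives, Ltf, Gpnmb and Rragd in 6 of 9 and Csf3 in 6 of 8. Arg2 (0.27 ± 0.10), Olr1 (0.68 ± 0.25) and Arg1 (-0.39 ± 0.19) were not called.

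By list, 6 of 15 mature surface genes were higher (7 adjusted over the list alone), 6 of 20 cytokine genes higher (8), 10 of 17 hypoxia genes lower (10), 5 of 17 glycolysis genes lower and 1 higher (8 and 1), 4 of 14 ER stress genes lower (6) and 4 of 16 immediate early genes lower (5, with 2 higher). These 6 lists were called by camera and none kept the call with an estimated correlation (adjusted p = 0.0921, 0.177, 0.0921, 0.21, 0.176 and 0.397 in that order). Of 15 granule genes 3 were lower and 2 higher (camera adjusted p = 0.241). Of 12 PMN-MDSC-associated genes 3 were higher and 2 lower (5 and 2 adjusted over the list alone; 0.241), which is not independent evidence. The count of 259 fell to 164, 127 and 107 without tumour replicates 1, 2 and 3, to 118 with replicates 2 and 3 summed, and to 58 by DESeq2. The balance turned with no filter on low counts (370 higher, 52 lower) and at 1000 UMIs per cell (206 higher, 187 lower). Ltf in this comparison had a log2 fold change of 0.56 at 1000 UMIs per cell.

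**Figure D4:**
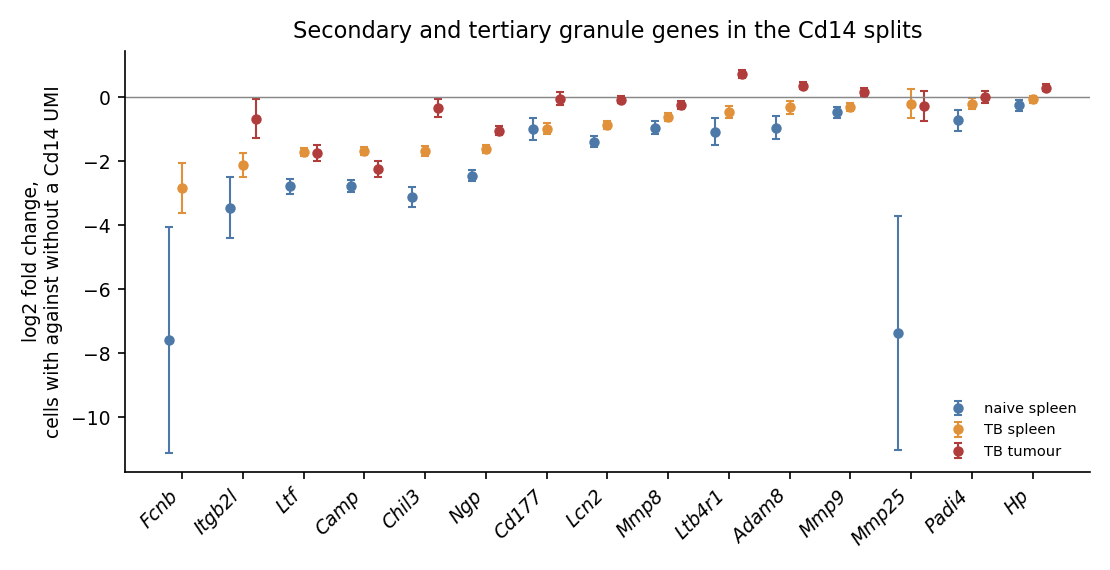
Log2 fold change (y axis, with SE) of the 15 secondary and tertiary granule genes (x axis) in cells with a Cd14 UMI against other neutrophil-like cells, in naive spleen, TB spleen and TB tumour. Points are fits over 2, 3 and 3 libraries, and Fcnb in tumour is left out because its SE could not be given. Camp and Ltf lie below 0 in all 3 groups.

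In human blood the question was how PMN of patients with a tumour differ from those of healthy donors. The 2 healthy libraries were unlike in depth, with a median of 452 UMIs and 288 genes per barcode in replicate 1 against 3007 and 1237 in replicate 2. The patient libraries had medians of 2727 and 2197 UMIs. Of 13412 gene identifiers 703 were called, 138 higher and 565 lower in patients (4030 at an unadjusted p under 0.05). The genes are not named because the human files give identifiers without symbols, and cells of all classes were summed. The count rests on single libraries, since leaving out either patient library left 3 or 1 calls, all higher, and leaving out either healthy library gave 7169 or 5212. Simulated changes of 2 on the log2 scale were not recovered at this sample size, and DESeq2 called 1747.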

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

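The difference between groups in this part was fixed before the data were examined, and the cluster below was singled out after its values were seen. The effect of a Cd14 UMI differed between tumour and TB spleen in 42 genes by the interaction test of edgeR (34 higher, 8 lower), of which 16 had an absolute difference of at least 1 on the log2 scale and a mean of at least 50 CPM. In these the tumour effect exceeded the spleen effect for the NADPH oxidase gene Cybb (1.83 ± 0.32, SE; adjusted p = 3.79e-05), Anxa3 (1.77), complement gene C3 (1.36), Chil3 (1.36), Ing4 (1.30), the leukotriene B4 receptor gene Ltb4r1 (1.17), Ckap4 (1.14), Mpc2 (1.10), Capns1 (1.08), Abracl (1.02), Aldh2 (1.02), Ly6c2 (1.01), Clec4a2 (1.00) and Scp2 (1.00). It was below the spleen effect for osteopontin gene Spp1 (-2.14) and heat shock gene Hsp90aa1 (-1.16). In most of these an effect was called in TB spleen and none in tumour. Examples are Cybb (-1.93 in the Cd14 cells of TB spleen and -0.1 in those of tumour), Anxa3 (-1.71 and 0.06) and Spp1 (2.21 and 0.07). Of the genes with the higher tumour effect, only Ltb4r1 was called in tumour itself (0.72). In TB spleen it stood at -0.46 and was not called. Hsp90aa1 stood at 0.42 in TB spleen, not called, and at -0.73 in tumour. Of the 15 granule genes 4 had a higher effect in tumour (9 adjusted over the list alone; adjusted p = 0.295 with an estimated correlation). DESeq2 called 2 genes higher and 5 lower, the opposite balance. The 2 splits are also unlike, since most tumour cells without a Cd14 UMI lost it by thinning. The edgeR count was 3 without TB spleen replicate 1, 22 without TB spleen replicate 2, 132 without TB spleen replicate 3, 22 without tumour replicate 2 and 23 without tumour replicate 3.

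A signal outside the comparisons was an unnamed cluster (cluster 15). Its leading genes held markers of neutrophils (G0s2), macrophages (Fn1 and Ccr2), platelets (Pf4 and Ppbp) and stromal cells (Dcn and Col3a1). Its barcodes had a median of 1549 UMIs, and stood at a median of 0.636 times their library's median. The cluster held 5.51% of barcodes (533 cells) in tumour replicate 3, 0.253% in tumour replicate 2, 0.012% in tumour replicate 1 and none in either spleen group. Whether its barcodes hold RNA of several cells was not tested.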

How the results depend on the processing

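The replicate block, both size factor choices, DESeq2, the gene filter, the cell filter, thinning, all barcodes and leaving out libraries were planned. Barcode set as a block, replicates 2 and 3 alone, summed tumour replicates, leaving out cells with markers of another class and no scaling factor were chosen after seeing the data. Where a count moved by over 1.5 times the cause was not tested. For TB spleen against naive spleen, none called became 55 with DESeq2, 132 with the replicate block, 67 with barcode set as a block, 18 in replicates 2 and 3 alone and 0 to 1 without a library. For tumour against TB spleen, 2972 became 4693 with the replicate block, 4883 with barcode set as a block, 1762 thinned and 1912 to 3140 without a library. For tumour against naive spleen, 3023 became 4425 with the replicate block, 4623 with barcode set as a block, 2011 thinned, 5526 with no scaling factor and 1960 to 3344 without a library. DESeq2 called 3024 and 3012 genes in the latter 2 comparisons, RLE gave 3031 and 3084, and summing tumour replicates 2 and 3 gave 2020 and 2060. All barcodes gave 3504 and 3037 calls there, but only 1751 of the 2972 and 1801 of the 3023 genes stayed called.

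In the Cd14 comparisons of naive spleen, TB spleen, tumour and their difference, DESeq2 called 19, 8, 58 and 7 genes. At 300 UMIs naive spleen gave 14 and tumour 153. At 1000 UMIs TB spleen gave 170, tumour 393 (206 higher, 187 lower) and the difference 128. With no gene filter tumour gave 422 (370 higher, 52 lower) and the difference 213, and with replicates summed 118 and 16. Without a library the ranges were 10 to 66 in TB spleen, 107 to 164 in tumour and 3 to 132 for the difference. Naive spleen is then left with 1 library, so no range is given. The human count of 703 became 1747 with DESeq2, 2709 with no gene filter, 858 with the replicate block (number pairs correlated at 0.03) and 1 to 7169 without a library, where the lone library of a group is assumed to vary like the other group. Thinning left out 1719 of 2739 barcodes of a healthy library. Of 45 list tests 29 passed, 29 with the replicate block, 15 with an estimated correlation and 23 with fry (21 of them in both).

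The differences in Cd14 share (3.06, 79.9 and 82.9 points for TB spleen against naive spleen, tumour against TB spleen and tumour against naive spleen) were 2.13, 70.7 and 72.8 at 300 UMIs, 6.94, 83.8 and 90.8 at 1000, and 15.1 and 91.8 for the comparisons with naive spleen unthinned. Without a library they ranged from 2.58 to 3.47, 78.4 to 82.6 and 81.5 to 85.7, and 27 to 31 of 42 shares were apart. Leaving out a library cannot make groups overlap that were apart, so that count could not fall below the 27 of all libraries and tests nothing. Reversed were Ndufb8 in tumour against naive spleen with all barcodes (0.22), Icam1 in the naive Cd14 comparison at 1000 UMIs (2.09) and Ltf in the tumour Cd14 comparison at 1000 UMIs (0.56). The shallowest library, naive replicate 3, held 169 neutrophil-like cells with 215736 UMIs. Not run without human gene names were the human CD14 comparison, gene lists, shares, classes and the mouse spleen calls in human. The stricter filter and Scrublet removed no mouse neutrophil-like cell, so that their mouse counts equal the reported ones by construction and test nothing. For single named genes, values kept their direction and their side of the threshold in 1370 settings for TB spleen against naive spleen (50 newly called), 1488 for tumour against TB spleen (8 newly called, 23 lost) and 1486 for tumour against naive spleen (19 newly called, 32 lost). In the Cd14 comparisons of naive spleen, TB spleen and tumour they did so in 367, 395 and 428 settings (9, 14 and 12 newly called, and 28, 12 and 68 lost).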

Other observations

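The tests of RNA from macrophage-like cells, of depth by thinning, of handling, of doublets and depth in naive spleen, and of other splits of the libraries were chosen after the results were seen. The largest rises in tumour were set against RNA from macrophage-like cells, deeper cells and handling of the tissue. Cd14 and the 12 largest rises, picked whatever their level in other cells, stood at a median of 2.12 times the plain CPM of the macrophage-like cells of the same libraries, against 0.029 for macrophage markers, which speaks against macrophage RNA for the set. Arg1, at 0.0147, lay below the marker median, Cxcl1, Spp1 and the named gene Thbs1 lay below the highest marker (0.780), and 8 of the 744 rises that met the naming rule without its condition on other cells lay at or below 3 times the marker median, so that macrophage RNA stays open for these. Of the named genes and Cd14, 13 of 13 were called higher with each cell thinned to 500 UMIs. These genes were picked as the largest rises in the same libraries, so that this outcome decides little about depth. The median depth of neutrophil-like cells was lower in tumour than in TB spleen in replicate 1 (3932 against 4261 UMIs). It was higher in replicates 2 and 3 (2356 against 1773 and 2402 against 1457). Immediate early and dissociation genes rose as well (adjusted p = 0.0235 with an estimated correlation), so handling of tumour tissue stays open beside a biological difference between tumour and spleen.

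The lower granule genes in spleen cells with a Cd14 UMI were set against the fixed number of UMIs, doublets and depth. When TB spleen cells were divided by 20 other genes of like share, 4 of them (Nrros, Il1rap, Cir1 and Prr5l) lowered the granule list as much as Cd14 did (-0.66; others -0.931 to 0.572). The fixed number of UMIs thus stays as an explanation in TB spleen, although the remaining genes lowered the list less or raised it. Naive spleen was not divided in this way. Without cells that carried 2 markers of another class the list's median was -0.968 ± 0.326 (SE) in TB spleen and -1.41 ± 0.411 in naive spleen. This speaks against doublets as the whole cause. The SE of a list's median is over its 14 or 15 genes taken as independent, and does not measure the spread between libraries. The bounds for doublets and depth used this SE, so they take no account of how libraries differ. Among cells between 0.5 and 2 times the median depth the list's median was -0.907 ± 0.257 in naive spleen (from -1.39). This speaks against depth as the whole cause there. In TB spleen the median was -0.5 ± 0.179 (from -0.883), at the bound set for it, so that depth cannot be told apart there. In that band 3 of 14 granule genes were called lower in naive spleen and 4 of 14 in TB spleen. Calls over all genes fell from 36 to 12 and from 55 to 8. The band also leaves out many cells of cluster 6, which is led by granule genes and has a median of 3.62 times its library's UMIs. Depth is thus not separated from the loss of these cells. Lower genes called in both TB spleen and tumour numbered 3 against 1.48 for independent lists.

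The spleen calls that appeared with the replicate block were set against RNA from other cells in the naive libraries. Of the 35 lower genes 28.6% (95% interval 14.6 to 46.3) were at least 3 times higher in the other cells, against 30.3% of all genes. This speaks against foreign RNA for the lower genes as a set, while foreign RNA stays open for the 10 genes above that bound. The 97 higher genes had a median fold of 2.96, against 1.07 that dilution by foreign RNA gives. Only large folds were called (the smallest was 1.86), so the bound set for the median is passed by selection. A dilution of 1.07 is still too small to give any of these folds, which argues against it as their whole cause.

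Each group comparison was repeated over all 10 ways to divide its 6 libraries into groups of 3. For TB spleen against naive spleen the real split called 0 genes, a count that all 10 splits reach by construction, so this test decides nothing. The highest other split gave 19, with both replicates 1 and TB spleen replicate 3 on one side. That split follows the barcode set in part, but the other splits with both replicates 1 on one side gave 0. With the replicate block the real grouping gave 132. For tumour against TB spleen and tumour against naive spleen only the real split, 1 of 10, reached its count, and the highest other split gave 0 in both. With 10 splits no share below 0.05 can be reached.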
